A study of Mus musculus with 14 samples.

How the data were processed

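Poly(A) RNA from mouse APT tumor organoids was sequenced from stranded libraries, per the labels' protocols. The deposited files hold whole-number counts per gene, 1 file per library, and the authors applied no normalization that the values show. Demultiplexing with bcl2fastq 2.20, FastQC, STAR, featureCounts, DESeq2 and the GRCm38 build are named per the submitters' processing notes, and the other versions and settings are not given in the sources used here. Set 1 files list 55421 genes, of which 26935 had no count in any library, and set 2 files list 17490, of which 198 had none. Both sets list 17487 genes in common, and no line without a gene name was found. Of 10467 genes with a mean of 5 CPM or more in set 1, 78 were not listed in set 2, and 0.45% of set 1 counts lay in genes not listed in set 2. Symbols and coordinates were taken from GENCODE M21 (GRCm38), which matched 55240 and 17471 of the listed genes.

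Groups were taken from the labels, with 3 libraries each of control 1 and hairpin 1 and 4 each of control 2 and hairpin 2. Total counts ran from 9272134 to 26284079. No pair of libraries within a set agreed within sampling noise: the lowest chi-square per gene was 24.5 in set 1 and 3.02 in set 2. Pearson correlations of log2 CPM across genes within groups were 0.868 to 0.987 in set 1 and 0.978 to 0.996 in set 2. CPM were counts divided by TMM-scaled totals, and they carry no correction for gene length. CPM of Xist and Ivl used the total counts. Set, and so any batch, is confounded with the hairpin, and no control library is shared.

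The following choices were made before the data were examined, except where said otherwise. Each set was tested alone with edgeR's quasi-likelihood test (edgeR 4.0.16, R 4.3.3), TMM factors, the filterByExpr filter, Benjamini-Hochberg adjustment and a threshold of 0.05 with no fold threshold. Calls shared by both hairpins were counted among the genes tested in both sets. A model of the 4 groups gave the average of both hairpin effects and their difference. Gene lists, 46 in all, were tested with camera (limma 3.58.1) at a preset correlation of 0.01 where 5 or more members were tested, which left 40 lists for hairpin 1, 38 for hairpin 2 and 42 for the average. Those described cover epithelial junctions, mesenchymal, intestinal stem, enterocyte, goblet and Paneth cells, fetal-like and regenerative epithelium, interferon-stimulated genes, glycolysis, cholesterol synthesis, ribosomal proteins, mitochondrially encoded genes and heterochromatin machinery. Adjusted p-values of genes come from edgeR and those of lists from camera unless another tool is named.

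Named genes followed a fixed rule. Kmt5c and Kmt5b were always named. For each hairpin, the 8 genes with the largest increase and the 8 with the largest decrease were taken among those past the threshold with a mean of at least 5 CPM, no overlap between the groups and an established symbol. The same conditions in both sets were to give 12 genes per direction, and opposite calls were to give 6 genes for the difference, and both parts were empty. From each list past the threshold, and always from the epithelial, mesenchymal, stem cell and fetal-like lists, up to 4 members with the smallest p were named. Some genes that met this rule are not reported here. Other genes are said to have been chosen after their values were seen. In the account of the difference between hairpins, genes already named elsewhere by the rule are given.

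Libraries with the same replicate number were checked for pairing by correlating their deviations from the group means. In set 2 the correlations were 0.249, 0.153, 0.247 and 0.598, all over the limit of 0.1, so the numbers were taken to pair the libraries. Libraries with different numbers among replicates 1 to 3 correlated at 0.108 to 0.216, and those that set a replicate 4 library against another number at -0.391 to -0.268. The correlations thus set replicate 4 apart and do little to part numbers 1 to 3. This pairing rests on the data and not on a statement in the labels.

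Alternatives were DESeq2's size factors, no filter on low counts, the DESeq2 Wald test (DESeq2 1.42.0), the replicate block, a fold threshold of 1.2, the model of all 14 libraries, leaving out each library, an estimated correlation and fry. Voom with library quality weights and leaving out both replicate 4 libraries of set 2 were added after the data were seen. So was leaving out genes on chromosomes 5, 12 and 13. An estimated correlation in the blocked fit of set 2 and without hairpin 1 replicate 1 was also added then. The test of lists that differed between hairpins, with all its alternatives, was added after the data were seen too. Chromosome medians used genes with a mean of at least 5 CPM, windows were 10 Mb, and positions were shuffled 10000 times. Trends over GC content, transcript length and level were removed with mgcv 1.9.3. Tables and figures were made with Python 3.11.15, pandas 2.3.3 and matplotlib 3.10.9.

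The tests were checked on simulated counts with known changes. Of genes changed by 1.5, 2 and 4-fold, 0, 0 and 34.8% were recovered in a simulation of set 1 (13250 genes tested), and 59.7, 85.1 and 98.5% in one of set 2 (13962 genes). For the average of both hairpins 35.8, 61.2 and 86.4% were recovered (14834 genes).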

Results

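RNA-seq counts were obtained from mouse small-intestinal tumor organoids, called APT organoids in the labels. They carried inducible short hairpin RNAs against Suv4-20h2 or were controls, titled shCtrl. Suv4-20h2, listed under the gene symbol Kmt5c, is an enzyme that methylates histone H4 at lysine 20, a mark of compact chromatin. Hairpin 1 targeted exon 4 and hairpin 2 targeted exon 9. Every group, both controls included, was given 0.5 µg/ml doxycycline for 4 days. Set 1 held 3 libraries of control 1 and 3 of hairpin 1, and set 2 held 4 libraries of control 2 and 4 of hairpin 2. Total counts were 17123887, 16265034 and 18088690 in control 1, and 23321606, 16897767 and 19364941 in hairpin 1. They were 22053702, 19837679, 26284079 and 25026350 in control 2, and 22624223, 25267211, 9272134 and 11956927 in hairpin 2. Ribosomal protein mRNAs took 7.13 to 12.3% of the counts in set 1 and 1.56 to 1.96% in set 2, and no test set the levels of one set against those of the other. Nothing in the labels says that replicates came from separate cultures, so p-values measure the spread between these libraries, which may be technical.

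The targeted gene was examined first, as a check of the labels. Kmt5c (ENSMUSG00000059851, GRCm38 chromosome 7, 4740115 to 4747514, plus strand) had 71.8 ± 4.25 CPM in control 1 and 58.0 ± 5.59 CPM in hairpin 1 (SD, n = 3 each). In set 2 it had 124 ± 6.41 CPM in control 2 and 108 ± 6.40 CPM in hairpin 2 (SD, n = 4 each). No hairpin library reached the lowest control library of its set. The values were 72.3, 75.8 and 67.3 CPM in control 1 against 53.6, 64.3 and 56.1 CPM in hairpin 1. They were 129, 121, 116 and 128 CPM in control 2 against 114, 111, 99.3 and 106 CPM in hairpin 2. The log2 fold change was -0.31 (SE 0.175) for hairpin 1, with an edgeR adjusted p of 0.80, and -0.20 (SE 0.062) for hairpin 2, with an adjusted p of 0.098. Neither passed the threshold of 0.05, and protein and histone marks were not analysed here, so the extent of depletion is not known. With the replicate number as a block, the hairpin 2 value was -0.20 with an adjusted p of 0.0074. The related enzyme gene Kmt5b had a log2 fold change of -0.08 for hairpin 1 (adjusted p = 0.96) and 0.14 for hairpin 2 (adjusted p = 0.43, and 0.043 with the replicate block).

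**Figure D1:**
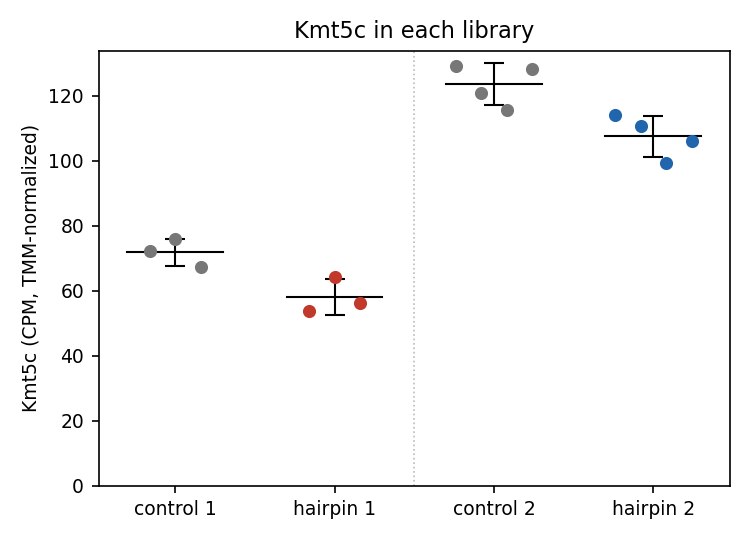
Kmt5c in CPM on the vertical axis for each library, by group; points are libraries, long lines are group means and bars are SD, and the dotted line parts set 1 from set 2. Hairpin 1 libraries lie at 53.6 to 64.3 CPM against 67.3 to 75.8 CPM in control 1, and hairpin 2 libraries at 99.3 to 114 CPM against 116 to 129 CPM in control 2.

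The first comparison asked which transcripts differed when exon 4 was targeted. No single gene passed the threshold, but 5 gene lists passed as groups at a preset correlation. Interferon-stimulated genes fell as a group, with all 29 tested members below 0 and a median log2 fold change of -0.83 (camera adjusted p = 5.4e-15, and adjusted p = 0.90 with an estimated correlation). Among them were Irf7, the transcription factor that amplifies type I interferon (132 ± 38.0 CPM in control 1 and 56.1 ± 14.7 CPM in hairpin 1, SD, n = 3 each), Oas2 (-1.67) and Xaf1 (-1.36). Ifit3b was at -2.28, but it has a near-identical copy and its count is uncertain. The mitochondrially encoded mRNAs rose as a group, with 7 of 7 above 0 and a median of 1.22 (adjusted p = 1.8e-04, and adjusted p = 0.90 with an estimated correlation), including mt-Co1 (0.99), mt-Nd4 (1.47) and mt-Cytb (1.24). They took 0.403 to 0.887% of the counts in control 1, and 0.56, 2.27 and 1.90% in the 3 hairpin 1 libraries.

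Fetal-like and regenerative markers also passed as higher (22 tested, median 0.72, adjusted p = 0.032, and adjusted p = 0.90 with an estimated correlation), with Clu at 1.37, S100a6 at 0.79 and Spp1 at 3.71. Hairpin 1 replicate 1 stood apart from the other libraries of set 1: its medians against control 1 were -4.82 for Paneth cell genes, -4.39 for goblet cell genes and 1.47 for fetal-like markers. Without it, this list passed in the opposite direction (adjusted p = 0.029, and adjusted p = 0.84 with an estimated correlation), and the log2 fold change went from 3.71 to 0.17 for Spp1, from 2.36 to -0.62 for Il33 and from 0.79 to 0.41 for S100a6. Spp1 had 18.95 CPM in that library, 0.506 and 0.636 CPM in the other hairpin 1 libraries and 0.176 to 0.873 CPM in control 1. The adjusted p of the fetal-like list was 0.117 without control 1 replicate 2 and 0.112 without its replicate 3. Ribosomal protein genes passed as lower (48 tested, median -0.15, adjusted p = 0.032, and adjusted p = 0.90 with an estimated correlation), for example Rpl5 (-0.53) and Rps6 (-0.37). Their adjusted p was 0.920, turned upward, without hairpin 1 replicate 1, 0.0979 without its replicate 2, and 0.813 without control 1 replicate 3. The glycolysis list passed as lower (18 tested, median -0.26, adjusted p = 0.039, and adjusted p = 0.90 with an estimated correlation), with the lactate exporter gene Slc16a3 at -1.79, Eno1 at -0.65 and Pfkl at -0.61. In hairpin 1 replicate 1 the median of this list was 0.69 above control 1, against -0.83 in the other hairpin 1 libraries. Without that library Pfkm went from 2.00 to -0.10, Eno1 to -0.98 and Pfkl to -0.99. The glycolysis adjusted p was 0.353 without control 1 replicate 1, 0.750 without hairpin 1 replicate 2 and 0.394 without its replicate 3. For the mitochondrially encoded list it was 0.0523 without control 1 replicate 2, and the interferon list passed on leaving out any single library. No member of these 5 lists passed alone, and 0 did when adjusted over the list alone.

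With all libraries, the epithelial junction, mesenchymal, intestinal stem, enterocyte and goblet cell lists did not pass for hairpin 1. The epithelial junction list (29 tested, median 0.01, adjusted p = 0.38) held Dsc2 at 0.72, the cadherin gene Cdh1 at 0.46, Dsg2 at 0.48 and Krt18 at -0.39. Of the mesenchymal markers (8 tested, median -0.22, adjusted p = 0.83), 1 was higher when adjusted over the list alone. Its members included Itga5 at 1.77, Vim at -0.85, Tgfbi at -0.92 and Postn at -1.21. The intestinal stem cell list (21 tested, median 0.09, adjusted p = 0.41) held Cd44 at 0.95, Lrig1 at 0.69, Znrf3 at 0.54 and Slc12a2 at 0.49. Without hairpin 1 replicate 1, Dsg2 was at 0.27, Vim at -0.51, Tgfbi at -0.48, Postn at -0.66, Cd44 at 0.63 and Znrf3 at 0.31. The enterocyte and goblet cell lists then passed as higher at the preset correlation (camera adjusted p = 0.023 and 1.5e-10). With an estimated correlation in that fit, their adjusted p-values were 0.79 and 0.48. With hairpin 2 both lists were lower, as given below.

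The edgeR quasi-likelihood test found 0 of 13540 genes past an adjusted p of 0.05 for hairpin 1, with 733 at an unadjusted p under 0.05 and a smallest adjusted p of 0.80. DESeq2 called 18 genes, limma voom with library quality weights called 8, and a model of all 14 libraries called 187. Without hairpin 1 replicate 1, edgeR called 1 gene, Atg9b (-1.81, adjusted p = 0.031), which was chosen after its value was seen. The lists numbered 5 of 40 with the preset correlation and 0 with an estimated one. They numbered 13 without hairpin 1 replicate 1, of which 0 passed with an estimated correlation, 8 without its replicate 2 and 10 without its replicate 3. The 9 other splits of these libraries into groups of the same size gave 11 to 17 lists each at the preset correlation.

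The comparison for exon 9 asked the same question in set 2. Of 11 tested enterocyte markers 5 fell with hairpin 2, and more genes fell over 2-fold than rose over 2-fold. Krt20, a keratin of differentiated intestinal epithelium, went from 42.5 ± 3.77 CPM in control 2 to 6.86 ± 1.21 CPM in hairpin 2 (SD, n = 4 each). Hnf4a, a transcription factor of intestinal differentiation, went from 295 ± 17.9 to 143 ± 28.4 CPM (SD, n = 4 each). In all, 854 of 14126 genes passed the edgeR test, 288 higher and 566 lower. Of these, 283 were over 2-fold lower and 21 over 2-fold higher, and 120 were over 4-fold lower against 0 over 4-fold higher.

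The named genes with the largest decreases were Trim35 (-4.89), Dynlt3, which encodes a dynein light chain (-4.74), the tyrosine kinase gene Ptk2b (-4.72), Bex1 (-4.63) and Rgl3 (-4.62). They were followed by Itih5 (-4.32) and the purinergic receptor gene P2ry1 (-3.90). Dynlt3 had 30.6 ± 1.38 CPM in control 2 and 1.28 ± 0.747 CPM in hairpin 2, and Bex1 had 48.3 ± 2.17 and 2.06 ± 0.789 CPM (SD, n = 4 each). The mucin gene Muc3 was at -4.39, but it has near-identical relatives and its count is uncertain. Among the genes that rose were the hair keratin gene Krt34 (1.72), the neural adhesion gene Chl1 (1.63), the glypican gene Gpc3 (1.51), Dapl1 (1.33), Tchh (0.87) and Pax3 (0.82). Chl1 went from 4.17 ± 0.263 to 12.9 ± 0.301 CPM and Ppargc1a, a coactivator of mitochondrial genes, from 4.59 ± 1.36 to 12.5 ± 0.796 CPM (SD, n = 4 each). The edgeR adjusted p-values of these genes ran from 1.7e-06 for Bex1 to 0.031 for Pax3.

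The enterocyte list fell, with 5 of 11 tested members lower, also 5 when adjusted over the list alone (median -0.35, adjusted p = 1.4e-11, and adjusted p = 0.040 with an estimated correlation). With the replicate block, the adjusted p of this list was 0.44 with an estimated correlation. The lowered members included Fabp2, for fatty acid binding (-3.59), Krt20 (-2.65), the glucose transporter gene Slc5a1 (-2.02) and Hnf4a (-1.04), and the fifth, chosen after its values were seen, was Mgam (-0.90). The goblet cell list fell, with 4 of 12 lower and 5 when adjusted over the list alone (median -0.45, adjusted p = 0.0025, and adjusted p = 0.80 with an estimated correlation). The lowered members were Guca2a (-3.45), Creb3l1 (-0.96), Clca1 (-0.55) and Galnt12 (-0.51). Fetal-like and regenerative markers fell, with 4 of 22 lower and 10 when adjusted over the list alone (median -0.22, adjusted p = 6.6e-07, and adjusted p = 0.31 with an estimated correlation). Il1rn (-2.84), Msln (-1.54), Emp1 (-1.18) and Sprr1a (-1.13) were the lowered members.

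**Figure D2:**
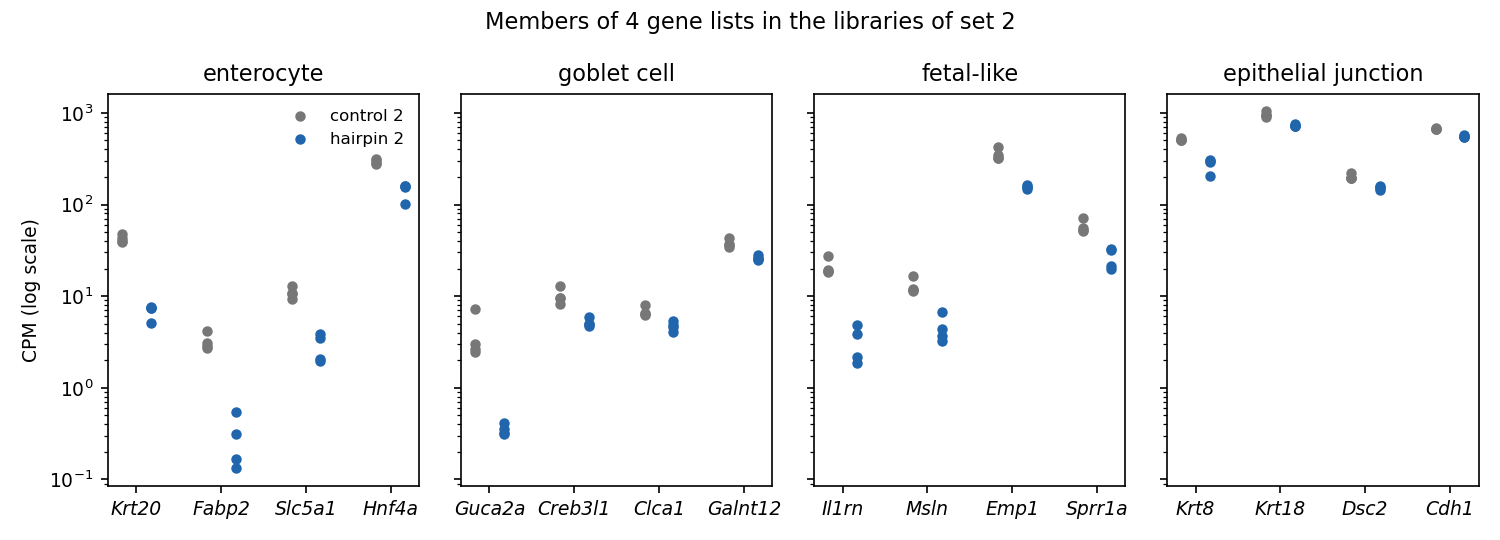
CPM on a log vertical axis for named members of 4 lists along the horizontal axis; each point is 1 library, gray for control 2 and blue for hairpin 2. All 4 hairpin 2 libraries lie below all 4 control 2 libraries for Krt20, at 5.05 to 7.62 CPM against 39.1 to 47.3 CPM.

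Epithelial junction genes fell by less, with 5 of 29 lower and 8 when adjusted over the list alone (median -0.09, adjusted p = 0.0060, and adjusted p = 0.80 with an estimated correlation). These were the keratin genes Krt8 (-0.89) and Krt18 (-0.41), the desmosomal gene Dsc2 (-0.40), Cdh1 (-0.28) and, chosen after its values were seen, Dsg2 (-0.28). Glycolysis genes fell, with 4 of 18 lower, also 4 when adjusted over the list alone (median -0.06, adjusted p = 0.022, and adjusted p = 0.80 with an estimated correlation). Pfkp (-1.89), Slc16a3 (-0.49), Pfkm (-0.33) and Slc16a1 (-0.32) were lower. Ribosomal protein genes fell as a group with no member past the threshold, and 0 adjusted over the list alone (49 tested, median -0.13, adjusted p = 0.0025, and adjusted p = 0.80 with an estimated correlation). Cholesterol synthesis genes did so too, with 0 adjusted over the list alone (25 tested, median -0.17, adjusted p = 0.022, and adjusted p = 0.84 with an estimated correlation). The closest to the threshold were Rpl34 (-0.35, adjusted p = 0.052) and Stard4 (-0.36, adjusted p = 0.051), which passed with the replicate block (1.7e-04 and 0.0020). The cholesterol adjusted p was 0.589 without hairpin 2 replicate 4 and 0.0612 without control 2 replicate 3, and the ribosomal one was 0.0512 without hairpin 2 replicate 3. Ribosomal protein mRNAs took only 1.56 to 1.96% of the counts in set 2, against 7.13 to 12.3% in set 1. The cause was not tested, so the counts of this list in set 2 are uncertain.

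Of the intestinal stem cell markers, 4 of 20 fell: Lrig1 (-0.99), a regulator of growth factor receptors, Ephb2 (-0.41), Msi1 (-0.30) and Smoc2 (-0.27). Adjusted over the list alone, 4 were lower and 1 was higher, and the list as a whole did not pass, with a median just above 0 (0.003), a mean of -0.09 and a test pointing down (adjusted p = 0.27). Mesenchymal markers did not pass as a group (9 tested, median 0.04, adjusted p = 0.52), nor did any member, and 0 did when adjusted over the list alone. Vim was at 0.41, Snai2 at 0.70, Col1a1 at -0.69 and Thbs1 at 0.10. Of 26 heterochromatin machinery genes, 1 rose, also 1 when adjusted over the list alone (adjusted p = 0.28 for the list). It was the DNA methyltransferase gene Dnmt3a (0.26), chosen after its values were seen.

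With the replicate number as a block in set 2, 2880 genes passed, 1447 higher and 1433 lower, including 853 of the 854. Mitochondrially encoded mRNAs (adjusted p = 0.0025) and Paneth cell genes (adjusted p = 0.0025) then passed as lower, and TGF-beta and BMP targets as higher (adjusted p = 0.036). With an estimated correlation in the same blocked fit, their adjusted p-values were 0.61, 0.44 and 0.44, and no list passed. Without the block and at the preset correlation they were 0.088, 0.11 and 0.058. The lists past the threshold without it numbered 7 of 38, all lower, against 1 with an estimated correlation, 4 with fry and 12, of which 3 were higher, without hairpin 2 replicate 4. The 4 with fry held the enterocyte and fetal-like lists of the 7, the inflammatory and NF-kB targets as lower and the TGF-beta and BMP targets as higher. The number of genes was 516 without control 2 replicate 1, 453 without its replicate 2, 526, 473 and 564 without hairpin 2 replicates 1, 2 and 3, and 1409 without hairpin 2 replicate 4. It was 2396, 1121 higher and 1275 lower, without both replicate 4 libraries, an alternative chosen after the data were seen. Of the named genes, Clca1, Msi1, Pfkm and Dnmt3a lost their calls in 7 of 8 leave-one-out fits, Dsg2 in 6, Smoc2 in 5, Pax3 in 4 and Slc16a1 in 2, with adjusted p-values up to 0.152.

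Medians over whole chromosomes also differed in set 2. Genes on chromosomes 5, 12 and 13 had medians higher by 0.11, 0.12 and 0.17 on the log2 scale in hairpin 2, against differences of -0.05 to 0.04 on the others. In each of the 3, all 4 pairs of equal replicate number were higher in hairpin 2. An exact two-sided permutation test within the pairs gave p = 0.125 for each, the smallest that 16 labelings allow, so it cannot reach 0.05. Of the 17 other chromosomes, 14 with smaller differences reached the same p. Medians were centered per library. In set 1, hairpin 1 replicate 1 alone had a chromosome 12 median of 0.67 and a chromosome 14 median of -0.71, against -0.13 to 0.18 for its other chromosomes. Krt20, Bex1 and Hnf4a lie on none of these chromosomes, while Trim35 and Ptk2b lie side by side on chromosome 14. Of the genes named above that passed for hairpin 2, Muc3, Ppargc1a, Slc5a1 and Msi1 lie on chromosome 5, Dnmt3a on chromosome 12 and Pfkp on chromosome 13. Dnmt3a was higher by 0.26, on a chromosome whose median was higher by 0.12.

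**Figure D3:**
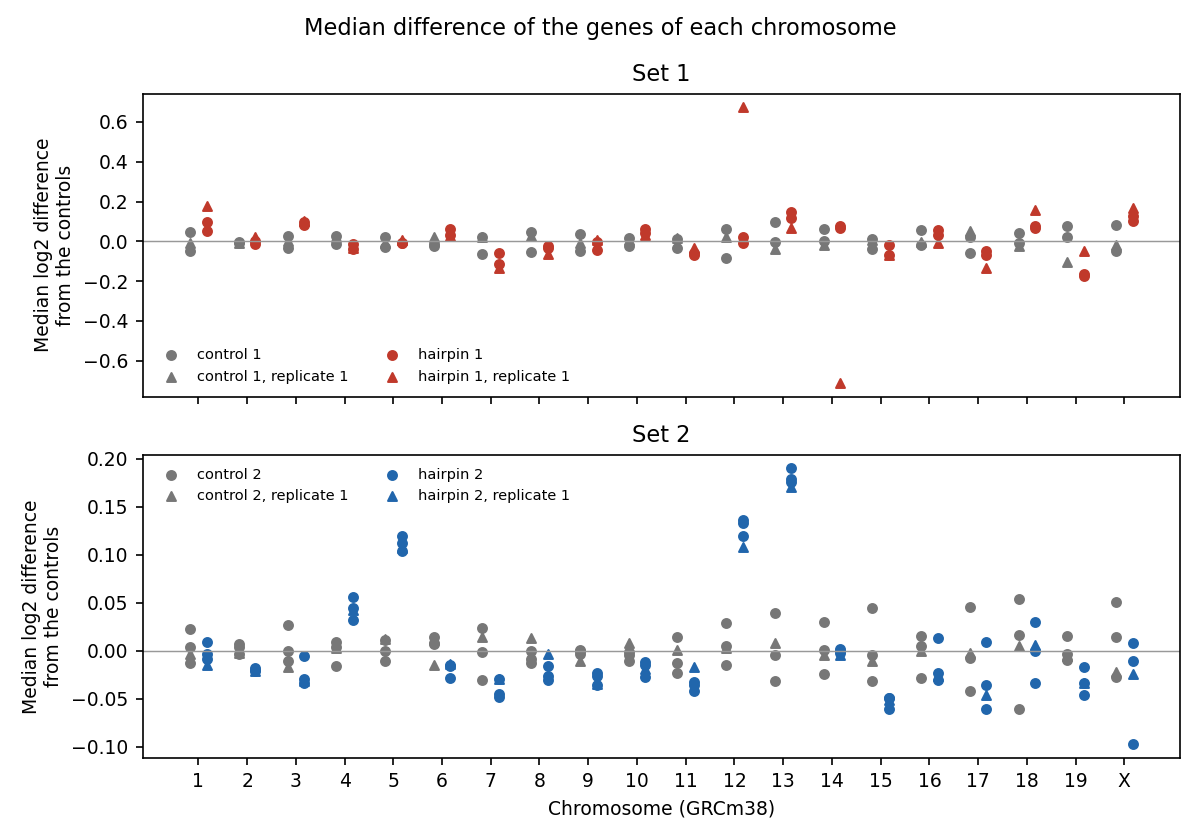
Median log2 difference from the controls of the set on the vertical axis for the genes of each chromosome (horizontal axis), centered per library; each point is 1 library (gray controls, red hairpin 1, blue hairpin 2), each control is compared with the other controls, and triangles are replicate 1. Hairpin 1 replicate 1 lies apart at chromosomes 12 and 14 (0.67 and -0.71), and all 4 hairpin 2 libraries lie above the controls at chromosomes 5, 12 and 13.

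The use of hairpins against different exons asks which changes both share. No gene was called for both hairpins by edgeR among the 12384 tested in both sets, where hairpin 1 had 0 calls and hairpin 2 had 249 higher and 491 lower. DESeq2 gave 1 shared gene, Myl7, and voom with quality weights gave 2, Myl7 and Sprr2a3, all lower and chosen after their values were seen. Independent lists of these sizes would share 0.5 and 0.6 lower genes (one-sided Fisher's exact p = 0.38 and 0.10). These overlaps are thus not told apart from chance. Of the 740 hairpin 2 calls, 475 (64.2%) had the same direction for hairpin 1, with an exact one-sided permutation p of 0.10 over 20 labelings, of which the smallest possible is 0.05. Without hairpin 1 replicate 1 it was 405 genes (54.7%), with an exact p of 0.40, of which the smallest possible is 0.10.

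For the average of both hairpins, interferon-stimulated genes fell as a group, with all 29 below 0, 1 lower alone and 7 when adjusted over the list alone (median -0.62, adjusted p = 4.7e-10, and adjusted p = 0.99 with an estimated correlation). With hairpin 2 alone this list did not pass (20 tested, 3 lower, also 3 when adjusted over the list alone, median -0.14, adjusted p = 0.11). The list fell less with hairpin 2 than with hairpin 1 (median difference 0.643, camera adjusted p = 0.0093, and 0.998 with an estimated correlation). That test was chosen after the data were seen. The lowered member for the average was Dhx58, a regulator of RNA sensing (-1.28, adjusted p = 0.030). Its log2 fold change was -0.72 for hairpin 1 and -1.86 for hairpin 2. Mx2 (-2.27), Irf7 (-0.86) and Ifi27 (-1.39) had adjusted p-values of 0.057 to 0.061 for the average. Il1rn of the fetal-like list was also lower for the average (-1.31, adjusted p = 0.023), but it was at 0.14 for hairpin 1 (adjusted p = 0.94) and -2.84 for hairpin 2, and the hairpins differed (-2.91, adjusted p = 0.014). Ribosomal protein genes (49 tested, median -0.17, adjusted p = 0.0012), cholesterol synthesis genes (25 tested, median -0.16, adjusted p = 0.034) and glycolysis genes (18 tested, median -0.19, adjusted p = 0.041) passed as lower. No member of these 3 lists passed, 0 did when adjusted over the list alone, and each list had an adjusted p of 0.99 with an estimated correlation. Examples were Rpl13 (-0.34), Fdps (-0.46) and Pfkp (-1.03). The ribosomal list has the limit given for hairpin 2, the low share of these genes in the counts of set 2. Of cell identity markers, Krt18 was at -0.40, Krt8 at -0.44, Cd44 at 0.53 and Itga5 at 0.91, with adjusted p-values of 0.066 to 0.093.

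In this model 147 of 15043 genes passed, 51 higher and 96 lower, and 77 of them also passed for hairpin 2 alone. Of the 137 tested in both sets, 122 had the same direction in both, which selection for a large average itself favors. The model takes 1 spread for both sets. Its common coefficient of variation between libraries was 0.273, against 0.41 in set 1 and 0.119 in set 2 fitted alone. It thus understates the spread of set 1 and overstates that of set 2, so its p-values are approximate. The number of genes that passed was 1320 without hairpin 1 replicate 1 and 69 without its replicate 2. It was 63 and 549 without control 1 replicates 1 and 2, 47, 42, 45 and 47 without control 2 replicates 1 to 4, and 44, 43, 56 and 53 without hairpin 2 replicates 1 to 4. Dhx58 lost its call in 9 of 14 leave-one-out fits and Il1rn in 5, with adjusted p-values up to 0.0776. The number of lists, 4 of 42, was 0 with an estimated correlation. It went to 8 without hairpin 1 replicate 2, to 7 without control 2 replicate 1 and to 2 without control 2 replicate 3. The ribosomal adjusted p was 0.136 without control 1 replicate 3 and 0.447 without hairpin 1 replicate 1. The glycolysis one was 0.188 without control 1 replicate 1, 0.496 and 0.221 without hairpin 1 replicates 2 and 3, 0.0693 without control 2 replicate 3 and 0.0833 without hairpin 2 replicate 4. The cholesterol one was 0.0718 and 0.397 without control 1 replicates 2 and 3, 0.235 and 0.0759 without hairpin 1 replicates 1 and 2, 0.0693 without control 2 replicate 3 and 0.271 without hairpin 2 replicate 4.

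Whether the hairpins differed was tested in the same model. Fabp2 (-4.98, SE 0.64), Dynlt3 (-4.80, SE 0.50), Rgl3 (-4.23, SE 0.43) and Ptk2b (-4.12, SE 0.49) were lower with hairpin 2 relative to hairpin 1, with edgeR adjusted p-values of 8.8e-04 to 0.0046. So were the desmosomal gene Dsc2 (-1.13, adjusted p = 0.013) and the stem cell marker Lrig1 (-1.70, adjusted p = 0.036). In all 62 genes differed, 7 higher and 55 lower with hairpin 2, with 1808 at an unadjusted p under 0.05. Of the 62, 45 were called for hairpin 2 alone. The number was 959 without hairpin 1 replicate 1, 94 without its replicate 3 and 248 without control 1 replicate 2. It was 34, 33, 30 and 37 without control 2 replicates 1 to 4 and 27 and 28 without hairpin 2 replicates 1 and 2. Fabp2 had 6 to 65 counts per library in set 1. Lrig1 lost its call in 10 of 14 leave-one-out fits, with adjusted p-values up to 0.0948. As for the average, the model takes 1 spread for both sets, so these SEs and adjusted p-values are approximate. Each hairpin was measured only in its own set. Xist, the RNA of the inactive X chromosome, had 228 to 542 CPM in set 1 and 0 to 0.335 CPM in set 2, while the labels give both sets the same organoid name and number them as different clones. The hairpin, the set and any difference between the clones cannot be told apart, for the average as for the difference.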

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

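The test of genes that differed between hairpins was planned. The test of lists that differed, and leaving out libraries from it, were chosen after the data were seen. In groups of 4 libraries, a library counted as standing apart when its gap to the nearest other one took most of the range of the group by Dixon's criterion, on log2 CPM. This marked 24 of 194 groups, where chance marks about 1 in 20, and 18 of the 24 were replicate 4 libraries, 8 in control 2 and 10 in hairpin 2.

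In control 2, replicate 4 was higher for Spp1 (2.86, nearest other 1.96), mt-Nd4 (9.99, 9.33), Il1rn (4.77, 4.28), Msln (4.06, 3.58), Pmvk (6.36, 6.16) and Zg16 (2.81, 1.40), and lower for Lrig1 (5.75, 6.16) and Znrf3 (7.24, 7.47). Control 2 replicate 3 was higher for Dsc2 (7.78, 7.62) and lower for Rps18 (6.23, 6.52).

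In hairpin 2, replicate 4 was higher for Spp1 (3.63, nearest other 2.15) and Vegfa (10.48, 10.16), and lower for Eno1 (9.44, 10.07), Pfkl (9.18, 9.62), Lrig1 (4.58, 5.17), Krt8 (7.66, 8.20) and Hnf4a (6.66, 7.27). It was also lower for Ephb2 (6.36, 6.59), Mvd (6.57, 7.04) and Acat2 (5.56, 6.34). Replicate 2 was lower for Ppargc1a (3.51, 3.68) and Krt20 (2.36, 2.90), replicate 1 was higher for Krt18 (9.55, 9.49) and replicate 3 was higher for Vim (2.52, 2.2).

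The hairpins differed for 9 named genes by edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment, in the model with 1 spread for both sets. All were lower with hairpin 2 relative to hairpin 1. The log2 differences were -4.80 for Dynlt3, -4.12 for Ptk2b, -6.31 for Bex1, -4.23 for Rgl3, -4.08 for P2ry1, -1.13 for Dsc2, -1.70 for Lrig1, -2.91 for Il1rn and -4.98 for Fabp2, with adjusted p-values up to 0.0499 (Bex1). Bex1 had too few counts to be tested in set 1 alone, with 0 to 6 per library there and 42 in hairpin 1 replicate 2. Without that library its difference was -2.46 (adjusted p = 0.43), and it lost its call in 12 of 14 leave-one-out fits. Lrig1 lost its call in 10, with adjusted p-values up to 0.0948. By camera, 5 lists differed at the preset correlation, and each had a higher adjusted p with an estimated correlation. Median differences were -0.195 for epithelial junction genes (adjusted p = 0.040, and 1.00 with an estimated correlation), -1.03 for fetal-like markers (3.0e-05, and 0.95) and 0.643 for interferon-stimulated genes (0.0093, and 1.00). They were -0.843 for inflammatory and NF-kB targets (0.0014, and 0.27) and -1.46 for mitochondrially encoded genes (4.1e-04, and 0.95). The fetal-like difference rested on hairpin 1 replicate 1, without which its adjusted p was 0.416. The epithelial junction one was 0.178 without that library, 0.318 without control 1 replicate 2 and 0.106 without hairpin 2 replicate 4. The interferon one was 0.415 without control 1 replicate 2 and 0.186 without hairpin 1 replicate 3, and the mitochondrial one was 0.0570 without control 1 replicate 2. The inflammatory list kept its call on leaving out any single library.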

How the results depend on the processing

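Voom with quality weights, leaving out both replicate 4 libraries, leaving out chromosomes 5, 12 and 13, an estimated correlation in the blocked fit or without hairpin 1 replicate 1, and all settings for lists that differed were chosen after the data were seen. For hairpin 1, the 0 genes called by edgeR (733 at an unadjusted p under 0.05) became 18 with DESeq2, 8 with voom, 187 in the model of all libraries and 0 to 1 on leaving out a library. For hairpin 2, 854 genes became 1321 with DESeq2, 2880 with the replicate block, 331 with a fold threshold of 1.2, 2466 with voom, 120 in the model of all libraries and 2396 without both replicate 4 libraries. Leaving out single libraries gave 453 to 1409, and leaving out chromosomes 5, 12 and 13 gave 642. The mean effect went from 147 genes to 716 with DESeq2, 31 with the fold threshold, 1710 with voom and 42 to 1320 on leaving out a library. The difference went from 62 to 398 with DESeq2, 1323 with voom and 27 to 959 on leaving out a library. Genes shared by both hairpins went from 0 to 1 with DESeq2 and 2 with voom. Lists for hairpin 1 went from 5 to 0 with an estimated correlation, with or without hairpin 1 replicate 1, 0 with fry, 9 without a filter, 9 with the replicate block and 5 to 13 on leaving out a library. Lists for hairpin 2 went from 7 to 1 with an estimated correlation, 0 with it in the blocked fit, 4 with fry and 7 to 12 on leaving out a library. Lists for the mean effect went from 4 to 0 with an estimated correlation, 0 with fry and 2 to 8 on leaving out a library. Lists that differed between hairpins went from 5 to 0 with an estimated correlation, 1 with fry and 3 to 11 on leaving out a library. Other settings kept these counts within 1.5 times. Fewer libraries or genes enter some of these fits, and apart from that the cause was not tested.

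Kmt5c with hairpin 2 passed the threshold at -0.199 with the replicate block and at -0.172 with voom, and ran from -0.162 to -0.228 on leaving out a library. With hairpin 1 it ran from -0.250 to -0.388 and never passed. Kmt5b with hairpin 1 turned from -0.08 to 0.144 without control 1 replicate 3, 0.029 without hairpin 1 replicate 2 and 0.151 without hairpin 1 replicate 3, in a range of -0.447 to 0.151. Il33 turned to -0.620 without hairpin 1 replicate 1, in a range of -0.620 to 2.93, and to -0.579 with voom. Pfkm turned to -0.103 without that library, in a range of -0.103 to 2.75, and to -0.037 with voom. Vegfa turned from 0.33 to -0.550 with the replicate block, to -1.425 with voom and to -1.566 without hairpin 1 replicate 1, in a range up to 0.859. Ak4 turned from -0.13 to 0.281 and 0.284 without hairpin 1 replicates 2 and 3, in a range of -1.518 to 0.284. None of these 5 genes passed the threshold for hairpin 1, and the cause was not tested. Of 1982 values of named genes under alternatives, 1750 kept their direction and side of the threshold, 87 newly passed, 133 no longer passed and 12 turned, and 34 of the 133 came from the model of all libraries.

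In set 1 the same-number correlations were 0.231, -0.017 and 0.269, so the numbers were not taken to pair the libraries, and the replicate block called 0 genes there. In set 2 the replicate block also moved Kmt5b, Stard4, Sc5d, Pmvk, Rpl34, Rpl13, Rps18 and Rpl38 past the threshold. For the mean effect it moved Mx2 (adjusted p = 0.0445), Irf7 (0.0371), Cd44 (0.0371) and Pfkp (0.0262) past it. For the difference it ended the call of Bex1 (-5.71, adjusted p = 0.124), and it changed no other call of a gene named in the text for these comparisons. An alternative for normalized units was not run because the files hold counts.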

Other observations

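The genes of the first 2 paragraphs were chosen after their values were seen, as were the tests of a wrong label, copy number, chromosome gain, few counts, enterocytes, neighboring genes, lower depth as the whole cause and splits for lists that differed. In hairpin 2, genes of fatty acid oxidation moved both ways, with 2 of 18 higher and 3 lower, or 3 and 6 when adjusted over the list alone (camera adjusted p = 0.52). Ppargc1a (1.43) and Acot1 (0.38) rose, while the genes that fell included the peroxisomal gene Ehhadh (-1.08) and Cpt1a (-0.43), for mitochondrial fatty acid import. Of 20 inflammatory and NF-kB targets 3 fell, also 3 when adjusted over the list alone: Saa1 (-3.39), the chemokine gene Cxcl2 (-1.60) and Birc3 (-0.75), with an adjusted p of 0.088 for the list. Of 11 antigen presentation genes Tap1 (-1.17) and H2-K1 (-0.31) fell, and 3 did when adjusted over the list alone (adjusted p = 0.088 for the list). Car9, a carbonic anhydrase gene induced by hypoxia, fell (-2.76, edgeR adjusted p = 3.9e-06). For the average of both hairpins Car9 (-2.04, adjusted p = 0.0041) and the tyrosine kinase gene Fes (-1.25, adjusted p = 0.0023) were lower. The hypoxia response list as a whole did not pass for hairpin 2 (camera adjusted p = 0.24 with the replicate block). For the average it passed as lower at the preset correlation only in alternatives, such as the replicate block (adjusted p = 0.016). On leaving out 1 library of set 2 at a time, Saa1 lost its call in 4 of 8 fits, H2-K1 in 3 and Cpt1a and Tap1 in 2 each, with adjusted p-values up to 0.129.

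Without hairpin 1 replicate 1, hypoxia response genes (adjusted p = 7.0e-18) and glycolysis genes (adjusted p = 9.3e-15) were lower in hairpin 1 by camera, and mitochondrially encoded genes (adjusted p = 7.0e-18) and goblet cell genes (adjusted p = 1.5e-10) were higher, all at the preset correlation. With an estimated correlation in this fit, which was chosen after the data were seen, each of the 4 had an adjusted p of 0.48. No named member passed alone: Vegfa was at -1.57, Ak4 at -1.52, mt-Nd1 at 1.97 and Zg16 at 2.04, against 0.33, -0.13, 1.47 and 1.46 with all libraries. In hairpin 1 replicate 1 itself, the cornified envelope gene Ivl had 214.9 CPM, against 0.155 to 15.0 CPM in the other set 1 libraries. For Xist, which differed between the sets, the set 2 library with no count allows up to 0.324 CPM at 3 counts, for counting error alone.

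Hairpin 1 replicate 1 had a chromosome 12 median of 0.674 and a chromosome 14 median of -0.712, ratios of 1.60 and 0.611. After thinning of this library to the smallest total, its chromosome 12 median was 0.682. Random thinning leaves expected CPM unchanged, so this result was nearly fixed in advance and decides little about depth. Chance placement was argued against by shuffles (share 1e-04, the smallest they can give). A control library under a wrong label stays open: its correlation was at most 0.9044 with a control, against at least 0.961 between controls, but 0.868 and 0.871 with the other hairpin 1 libraries, so that it was far from both groups. A candidate explanation is a change of copy number of both chromosomes in this library. The shift ran along both, with 100% of their 24 windows shifted the same way. Both were picked for their medians, so the windows do not tell copy number from another shift of whole chromosomes. DNA was not analysed here, so a change of copy number stays a hypothesis.

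With hairpin 2, chromosomes 5, 12 and 13 had median log2 fold changes of 0.107, 0.119 and 0.180. Chance placement was argued against by shuffles (share 1e-04, the smallest they can give). Without the called genes the lowest median was 0.099, so the shift was present among genes not called. A median is little moved by a few strongly changed genes in any case, so this was no separate test of them. A trend over GC content, length and level was argued against as the whole cause by a lowest median of 0.106 after its removal. A candidate explanation is a gain of these chromosomes in part of the cells. The shift ran along them, with 97.4% of their 39 windows up against 42.7% of 225 elsewhere. These chromosomes were picked for their high medians, which itself favors such a contrast. The windows thus do not tell a gain from another shift of whole chromosomes. An effect of the hairpin and a difference between the organoid cultures that carry it were not separated by the design.

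With hairpin 2, 120 genes were over 4-fold lower and 0 over 4-fold higher. Noise of genes with few counts was argued against by 31 lower and 0 higher genes at 10 CPM or more. The enterocyte list had a median of -0.354 (SD 1.34, 11 genes), against -2.79 for the 120 genes. This cannot decide on fewer enterocytes as the whole cause, since the 120 genes were chosen for a fall over 4-fold. Of the enterocyte list, Fabp2 (-3.59), Krt20 (-2.65) and Slc5a1 (-2.02) fell over 4-fold too, while most members were not called. The lower depth of replicates 3 and 4 as the whole cause was argued against by 154 lower genes and 1 higher over 4-fold without these libraries. Of the 120 genes, 107 (89.2%) were over 4-fold lower in replicates 1 and 2 alone, just under the 90% set beforehand, against 81 in replicates 3 and 4, so that a small part for depth was not ruled out. Placement beside each other was tested for genes lowered over 2-fold, and not for the 120 genes or for raised genes. The test thus cannot decide whether placement has a part in the lack of raised genes. The 283 genes lowered over 2-fold held 11 neighboring pairs, such as Ptk2b and Trim35, against a mean of 5.36 in shuffles (share 0.0195). Pairs of gene families were left out only where the symbols began alike. Pairs such as Ugt1a7c with Gm15368 and Lypd8 with 1810065E05Rik could not be sorted this way, so families were not fully left out. Depletion of Suv4-20h2 remains open as an explanation and was not tested apart from the hairpin. Depletion itself was not shown here, since protein and histone marks were not analysed. Kmt5c mRNA with hairpin 2 did not pass edgeR without the block, and passed with the block (-0.199, edgeR adjusted p = 0.0074) and with voom (-0.172).

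Other splits of the libraries were counted as planned. For hairpin 2, with the pairing left aside, 1 of 35 splits, the real one, gave as many genes (854, highest other 0). This is the smallest share that 35 splits can give, and it argues against chance without excluding it. Only 8 splits part all 4 pairs, too few for a share under 0.05, and among them the real one gave 2880 genes with the replicate block and the highest other 0. For the mean effect 5 of 60 drawn splits gave as many genes (147, highest other 490). For the difference 4 of 60 did (62, highest other 369), so chance is not excluded for these counts. The split with 490 and 369 kept the real grouping of set 2, so it is no pure chance value. Apart from it the highest were 226 and 77. All counts above the real ones came from 1 split of set 1, which put control 1 replicate 2 with hairpin 1 replicates 2 and 3. Genes shared by both hairpins by edgeR were 0 in all 60 splits, the real one included, so this count excludes nothing. Lists were as many in 26 of 35 splits for hairpin 2 (7, highest other 15) and in 58 of 60 for the mean effect (4, highest other 21), so chance is not excluded for these counts. The same held for lists that differed between hairpins, a count tested after the data were seen (59 of 60 splits, real 5, highest other 21). Set 1 has 10 splits, too few for a share under 0.05, with 0 genes in the real one and at most 0 in the others. The real one gave 5 lists, the fewest, against 11 to 17 in the 9 others.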
